A study of Mus musculus with 3 samples.

How the data were processed

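Ascending aortas of 3 mice were pooled per library, digested with enzymes, sorted by flow cytometry for live singlets and processed with the 10x Genomics 3' v3 kit, per the labels' protocols, with a target of 10000 cells per sample. The deposited values are counts of UMIs per gene and barcode, which the authors made with Cell Ranger against mm10, per the submitters' processing notes; the version of Cell Ranger is not given in the sources used here. The matrices hold filtered barcodes and 32285 genes. Count matrices of WT AngII and StingKO AngII were used; the saline library, for which 16053 barcodes are listed, was not analysed here. Median depth was 10886 UMIs per barcode in WT AngII and 10385 in StingKO AngII. Coordinates come from GENCODE M21 on the same build, in which 32158 of the 32285 gene IDs have a place.

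Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, 11146 in WT AngII and 11511 in StingKO AngII. Doublets were scored per library against simulated pairs of cells, 2 per barcode, and the highest-scoring barcodes were removed at 0.8% per 1000 barcodes, which took out 1275 and 1367 cells; the sort for singlets does not remove doublets formed in droplets. The remaining cells of both libraries were log-normalised and clustered together without integration, on 2000 variable genes, 30 principal components, 20 neighbours and the Leiden method at resolution 1.0. Genes of the fixed lists and the marker table were left out of the variable genes, so that clusters were not formed directly by them. Genes outside the lists, among them ranked genes such as Zbtb16 and Wdfy1, were not left out. The naming of clusters did use the markers, and all smooth muscle markers are also members of the contractile list. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and leidenalg 0.10.2.

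Clusters were named from markers of 21 cell types fixed before the data were examined. A marker counted as raised where at least 25% of the cluster's cells had a UMI of it and its CPM was at least 2 times the median over clusters, and the type with the most raised markers gave the name. This scoring was set after the clusters had been seen: a first rule compared each cluster with all cells outside it and ranked types by the share of their markers raised, and it was replaced by comparison with the median cluster, by ranking on the number raised and by merging the macrophage and monocyte markers. Cells per library had been seen when some of these choices were made. A cluster stayed unnamed with fewer than 3 raised markers, with more markers of another type than its own among its 10 leading genes, or with a low median UMI count and none of its own markers among those genes. Clusters 10, 14, 15, 24 and 26 stayed unnamed.

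UMI counts were summed per class and library and expressed as CPM, relative to all UMIs of the class, in classes with at least 100 cells in each library. Levels have exact Poisson intervals, ratios exact conditional binomial intervals and shares Clopper-Pearson intervals, at 95%. They cover counting error only. With 1 library per group no p-value was computed. The 22 gene lists were fixed at the same time as the markers; a list is described by the median log2 ratio of its members with at least 50 UMIs, with a prior of 0.5 counts, and by the percentile of that median among 10000 random lists matched on expression in 20 bins, as a description of these libraries. Named genes followed a rule set at the same time: 12 genes in any case; in SMC-like cells the 8 highest and 8 lowest log2 ratios among genes with a mean of at least 20 CPM and 200 UMIs, without mitochondrial, ribosomal and predicted genes, the sex-chromosome genes Xist, Ddx3y, Eif2s3y, Kdm5d and Uty, and genes over 10 times higher in another class of at least 50 cells; and the 2 members of each list with the largest ratio. A gene that this rule names is not reported here. Other classes had the 4 highest and 4 lowest, with list members beside them. Fibroblast-like Adipoq and Saa3, SMC-like Lcn2 and phagocyte genes of the lists were picked after their values were seen. A count of 0 was set to a floor of 3 UMIs for a fold. The highest share of free RNA from fibroblasts in SMC-like cells was taken as the lowest ratio of SMC-like to fibroblast-like CPM in WT AngII among fibroblast markers with at least 500 UMIs, which was 0.502% for Clec3b. It takes all fibroblast-like clusters to release RNA alike, which was not tested.

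The calculations were tested on simulated counts for SMC-like cells, StingKO AngII against WT AngII, run on 32285 genes: among 10791 genes with no difference 95.4% of intervals held the true ratio, among 50 genes each made 1.5 times higher or lower it was 98.0% and 98.0%, and among 50 genes each made 3 times higher or lower it was 88.0% and 98.0%. The counts were simulated with counting error only, as the intervals assume, so they check the calculation and not the spread between mice or libraries. Alternatives tried were a looser cell filter (200 genes, 20%), a stricter one (1000 genes, 5%), no removal of doublets, clusters formed with the list and marker genes, resolution 0.5, separate clustering of the libraries, TMM factors, the mean over cells of CPM, thinning to 2000 UMIs, members with at least 500 UMIs or 1 UMI, and other cycle cutoffs.

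In fibroblast-like cells the lists not described at length in the results had these medians: contractile 0.09, identity regulators 0.16, structural matrix 0.00, proteolysis 0.05, TGF-beta and angiotensin 0.00, cytosolic DNA sensing 0.04, cell death -0.11, unfolded protein 0.19, oxidative stress -0.07, glycolysis -0.15, chondrogenic -0.76, resident macrophage -0.26, inflammatory monocyte -1.89, lipid-handling 0.06, fibroblast activation -0.26 and endothelial activation 0.00. In mononuclear phagocyte-like cells they were contractile 0.49, identity regulators 0.29, structural matrix -0.37, proteolysis -0.32, TGF-beta and angiotensin -0.09, cytosolic DNA sensing 0.08, interferon response -0.03, antigen presentation -0.20, inflammatory cytokines 0.11, cell death 0.00, unfolded protein 0.06, oxidative stress -0.05, chondrogenic -0.52, fibroblast activation -0.49 and endothelial activation 0.45.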

Results

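The transcriptomes of single cells from the ascending aorta of mice were measured with droplet-based 3' sequencing after 7 days of infusion. Wild-type mice received saline or angiotensin II, a vasoconstrictor peptide used to bring about aortic aneurysm and dissection in mice, and Sting-deficient mice received angiotensin II at the same 2000 ng/kg/min. STING, the product of Sting1, is an adaptor that relays the detection of cytosolic DNA to interferon and NF-kB signalling. Each of the 3 groups was 1 library made from 3 pooled mice, and live singlets had been sorted by flow cytometry. The count matrices used here were those of WT AngII, with 12708 barcodes and 161278100 unique molecular identifiers (UMIs), and StingKO AngII, with 13180 barcodes and 156391845 UMIs. The saline library was not analysed here, so no value below describes the effect of angiotensin II itself. With 1 library per group there was no replicate check and no test between genotypes. Intervals are exact 95% intervals that cover counting error only, not the spread between mice.

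The comparison of StingKO AngII with WT AngII addressed the role of STING in the state of smooth muscle cells (SMCs) during disease development. SMC-like cells of StingKO AngII had higher levels of contractile genes (median log2 ratio 0.24) and lower levels of inflammatory and adhesion genes (-1.79), interferon-response genes (-0.60) and antigen-presentation genes (-0.54) than those of WT AngII. The contractile list was also higher in mononuclear phagocyte-like cells of StingKO AngII (0.49), where free RNA from SMC-like cells was not weighed. Neutrophil-like cells were almost absent from StingKO AngII. Among mononuclear phagocyte-like cells, genes of resident macrophages were higher and genes of inflammatory monocytes lower in StingKO AngII. The inflammatory monocyte list was also lower in fibroblast-like (-1.89) and SMC-like cells (-1.39). The SMC-like value turned to 0.074 for members with at least 500 UMIs. Proliferation genes were lower in fibroblast-like cells of StingKO AngII, where other groupings of the cells were not tried. In SMC-like cells their direction depended on how the cells were grouped.

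The targeted gene, Sting1, is listed under its older symbol Tmem173 (ENSMUSG00000024349) and lies on chromosome 18 at 35733679 to 35740554 on the minus strand of mm10. Over all cells kept, its level was 23.6 CPM (22.7 to 24.4) in WT AngII and 11.3 CPM (10.7 to 11.9) in StingKO AngII. In SMC-like cells it was 3.58 CPM (3.04 to 4.19) and 1.15 CPM (0.887 to 1.45), a log2 ratio of -1.64. It was 78.4 and 46.4 CPM in mononuclear phagocyte-like cells and 22.0 and 13.1 CPM in fibroblast-like cells. The gt allele named in the labels is known as a point mutation, so a transcript level does not by itself check the genotype. Xist was close to absent in both libraries, with 8 and 14 UMIs, against 10071 and 12290 UMIs of the Y-linked gene Ddx3y.

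After filtering, 9871 cells of WT AngII and 10144 of StingKO AngII were clustered together and named from marker genes. SMC-like cells made up 31.4% (30.4 to 32.3) of WT AngII and 47.2% (46.2 to 48.2) of StingKO AngII. Fibroblast-like cells made up 35.1% (34.1 to 36.0) and 31.9% (31.0 to 32.8), and mononuclear phagocyte-like cells 21.5% (20.7 to 22.4) and 17.5% (16.8 to 18.3). Neutrophil-like cells, led by S100a8 and S100a9, numbered 191 in WT AngII, or 1.93% (1.67 to 2.23), and 5 in StingKO AngII, or 0.0493% (0.0160 to 0.115). Smaller classes held 43 and 32 endothelial-like, 49 and 49 dendritic-like, 25 and 3 Schwann-like and 3 and 19 mesothelial-like cells. Unnamed clusters held 8.87% of WT AngII and 2.38% of StingKO AngII. The largest of these, cluster 10, expressed SMC contractile genes together with Msx2 and Rgs5 and held 5.37% of WT AngII and 0.325% of StingKO AngII. With the limits on mitochondrial share and on genes changed together, to at most 5% and at least 1000, SMC-like cells made up 19.1% of WT AngII and 19.0% of StingKO AngII, and fibroblast-like cells 28.9% and 38.5%, so that their order turned. The sort for live singlets can also set such shares, and its effect was not tested. The named classes were rebuilt here and may differ from those of the study.

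**Figure D1:**
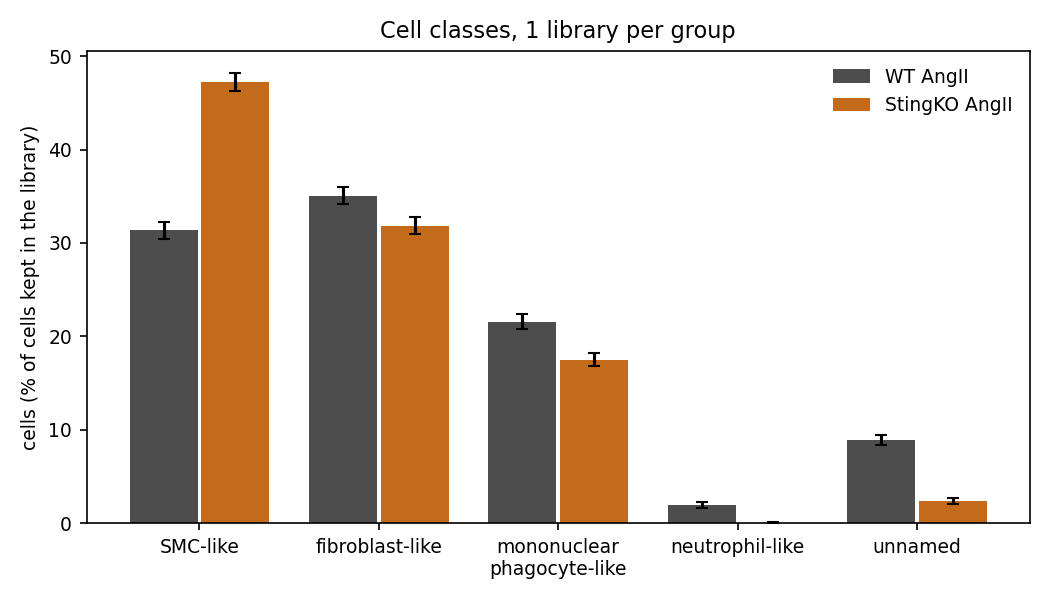
Share of the cells kept in each library (vertical axis, percent) by class, with WT AngII in grey and StingKO AngII in orange; bars are 1 library each and error bars are exact binomial 95% intervals for counting error only. SMC-like cells stand at 31.4% and 47.2%, and neutrophil-like cells at 1.93% and 0.0493%.

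In SMC-like cells (3095 in WT AngII and 4787 in StingKO AngII), 26 of the 28 measured contractile and cytoskeletal genes were higher in StingKO AngII. Their median log2 ratio was 0.24, above every one of 10000 random lists matched on expression. The same list had a median of 0.49 in mononuclear phagocyte-like cells (17 of 22 members higher) and 0.09 in fibroblast-like cells (15 of 28 higher). Free RNA from SMC-like cells was not weighed in these 2 classes, so their values need not describe their own expression. Whether the higher level was particular to SMC-like cells stays open. All smooth muscle markers that named the class are members of the list. Myh11, smooth muscle myosin heavy chain, was at 1848 CPM in WT AngII and 2803 CPM in StingKO AngII, a log2 ratio of 0.60 (0.59 to 0.61). Cnn1, which encodes calponin, had a log2 ratio of 0.35, and the actin gene Acta2 and its partner Tagln had ratios of 0.21 and 0.17. Ldb3, which encodes a Z-disc protein, had a ratio of 0.68. Myocd, the coactivator that drives the contractile programme, was also higher, with a log2 ratio of 0.74 (0.69 to 0.80), as was Klf4, a factor known to repress that programme, at 0.56 (0.51 to 0.61). The wider list of identity regulators and chromatin factors had 13 of 20 members higher and a median of 0.07, at percentile 86.1 of random lists. Its largest ratios were those of Tcf21 at -1.11 and of the proliferation factor Foxm1 at -0.82, which turned to 0.069 with each SMC-like cluster given the same weight. Tcf21 is also one of the fibroblast markers and was at only 5.18 CPM in WT AngII and 2.41 CPM in StingKO AngII. Part of its level may be free RNA from fibroblasts. The SMC-like class was spread over 6 clusters, and within single clusters the contractile median ran from 0.086 to 0.59. Over 4 bins of mitochondrial share the contractile median ran from 0.068 to 0.51. It was 0.38 with the strict cell filter and 0.16 with each cluster given the same weight, an alternative chosen after the data were seen.

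Inflammatory cytokine and adhesion genes showed the largest difference of the 22 fixed lists in SMC-like cells. Of 25 measured members 24 were lower in StingKO AngII, with a median log2 ratio of -1.79, below every random list. Within single SMC-like clusters the median ran from -2.34 to -0.46, and the median over the 6 clusters was -0.91. Over bins of 2 to 4, 4 to 6, 6 to 8 and 8 to 10% mitochondrial UMIs, looked at after the data were seen, it was -1.82, -1.24, -0.99 and -0.20, the last over 9 members. Vcam1, a leukocyte adhesion molecule, was at 242 CPM in WT AngII and 38.0 CPM in StingKO AngII, a ratio of -2.67 (-2.73 to -2.60). The acute-phase gene Saa3 had a ratio of -6.49 (-7.71 to -5.50). Cxcl5, a neutrophil-attracting chemokine, had 269 UMIs in WT AngII and 0 in StingKO AngII, 120-fold lower against a floor of 3 UMIs. The interval of its log2 ratio lay below -6.60. Cxcl3, another such chemokine, had 235 and 0 UMIs, 105-fold lower against the same floor, with an interval below -6.41. In WT AngII it was at 114 CPM in mononuclear phagocyte-like cells against 5.39 CPM in SMC-like cells, beyond the 10-fold limit of the ranking rule for another class. Saa3 and Cxcl5 were at 184 and 26.6 CPM in fibroblast-like cells of WT AngII. At the highest share the fibroblast markers allow, free RNA from that class would give 7.52% and 2.17% of their SMC-like level. Selp, which encodes P-selectin, had a ratio of -4.85 (-5.43 to -4.32); the endothelial activation list that holds it had 7 of 12 members lower and a median of -0.69, which turned to 0.050 with the strict cell filter. Type I interferon response genes were lower for 25 of 28 members, with a median of -0.60. They included Rsad2 at -2.48, from 83 UMIs in WT AngII and 20 in StingKO AngII, and Cxcl10 at -1.98. All 15 measured antigen presentation genes were lower, with a median of -0.54; the immunoproteasome subunits Psmb9 and Psmb8 had ratios of -1.38 and -1.36. Both lists lay below every random list. The interferon median was -0.20 with the strict cell filter, -1.07 with separate clustering and -0.37 with each SMC-like cluster given the same weight. The cytosolic DNA sensing list itself, which holds Sting1, showed no common direction, with 6 of 12 members higher and a median of -0.01. Cgas, the enzyme upstream of STING, had a ratio of 0.52 whose interval ran from -0.19 to 1.26.

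Structural matrix genes as a group were close to equal in SMC-like cells, with 21 of 35 members lower and a median of -0.02 that lay at percentile 69.4 of random lists and turned to 0.053 with the strict cell filter. Col3a1 had a log2 ratio of -0.01, Col1a1 -0.14 (0.020 with the strict cell filter), Eln, the elastin gene, 0.08 and Fn1, the fibronectin gene, 0.07. Single members were lower, among them Thbs1 at -1.39 (-1.43 to -1.35) and Fbln2 at -1.32. Fbln2 was beyond the 10-fold limit of the ranking rule for another class, so part of its level may be free RNA. Of the 24 measured proteolysis genes 17 were lower, with a median of -0.19 at percentile 0.890. Timp1, an inhibitor of matrix metalloproteinases, was at 797 CPM in WT AngII and 107 CPM in StingKO AngII, a ratio of -2.90 (-2.94 to -2.86), and the metalloproteinase Mmp3 had a ratio of -2.20. Spp1, the osteopontin gene and a marker of modulated SMCs, was at 917 CPM and 153 CPM, a ratio of -2.58 (-2.61 to -2.55). Chondrogenic and osteogenic genes were lower for 9 of 11 members (median -0.31). Its members Col2a1 and Prg4 had ratios of -3.72 and -2.96, from 2.71 and 12.9 CPM in WT AngII; they were at 75.4 and 287 CPM in its fibroblast-like cells, whose free RNA would give at most 14.0% and 11.1% of the SMC-like level by the fibroblast markers. The fibroblast activation list had 11 of 14 members lower and a median of -0.32, with Ddah1 at -1.43. TGF-beta and angiotensin signalling genes had a median of -0.06 (0.076 with the strict cell filter), with Smad6 at -0.78 and the endothelin gene Edn1 at -0.70.

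Cell cycle genes were lower for 27 of 30 members in SMC-like cells, with a median of -0.61, including Birc5 at -1.42 and Cdk1 at -1.28. After thinning to 2000 UMIs per cell, 6.54% (5.69 to 7.48) of WT AngII and 4.43% (3.87 to 5.06) of StingKO AngII SMC-like cells had at least 2 UMIs of the list; 23 and 5 shallower cells were left out, and the unthinned shares were 46.2% and 38.8%. At 1000 UMIs the shares were 4.11% and 2.72%, against 1.05% (0.128 to 3.75) in the neutrophil-like cells of WT AngII, which do not divide and had a median of 1527 UMIs. When each SMC-like cluster was given the same weight, an alternative chosen after the data were seen, the median of the list was 0.18, so the direction turned, and it was -0.011 with the strict cell filter and -2.46 with separate clustering. Values within groups of SMC-like cells were looked at after the data were seen. The median was 0.54 (29 of 30 members higher) among cells with 4 to 6% mitochondrial UMIs and 0.56 (21 of 23 higher) with 6 to 8%, which together held most SMC-like cells, but -0.46 (6 of 30 higher) with 2 to 4% and -0.44 (0 of 4 higher) with 8 to 10%. Within single clusters it ran from -0.28 to 0.20, and the highest was that of cluster 18, where 22 of 30 members were higher. Cell death and p53 response genes were lower for 18 of 22 members (median -0.30), with the inflammatory caspase gene Casp4 at -1.74. The inflammasome gene Nlrp3 had a ratio of -1.07 (-1.89 to -0.28). It rested on 36 UMIs in WT AngII and 23 in StingKO AngII, or 0.83 and 0.39 CPM. At this level its ratio need not describe SMC-like expression. Oxidative stress genes had a median of -0.11, with the haem oxygenase gene Hmox1 at -2.53 and the metallothionein gene Mt2 at -0.91. Hmox1 was beyond the 10-fold limit of the ranking rule for another class, so part of its level may be free RNA.

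Genes of SMC-like cells were ranked by a rule that leaves out those with a mean under 20 CPM and those over 10 times higher in another class. The highest by this rule was Zbtb16, a zinc-finger transcription factor, which was at 14.96 CPM in WT AngII and 86.8 CPM in StingKO AngII (log2 ratio 2.54, 2.42 to 2.66). Wdfy1 had a ratio of 2.05, Klf15, a transcription factor of metabolic control, 1.90, Irs2, an insulin receptor substrate, 1.63 and Pgf, the placental growth factor gene, 1.53. Nr4a2, the long noncoding RNA Neat1 and Rnf152 followed at 1.46, 1.25 and 1.22. The lowest by the rule were Timp1, Vcam1, Spp1, Thbs1 and Cdk1, given above, and Tnfrsf11b, which encodes osteoprotegerin, at -1.86, the Wnt inhibitor gene Frzb at -1.66 and Phlda1 at -1.32. Genes that the rule left out had lower ratios, among them Saa3, and Lcn2 at -6.03 (59.3 and 0.906 CPM).

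**Figure D2:**
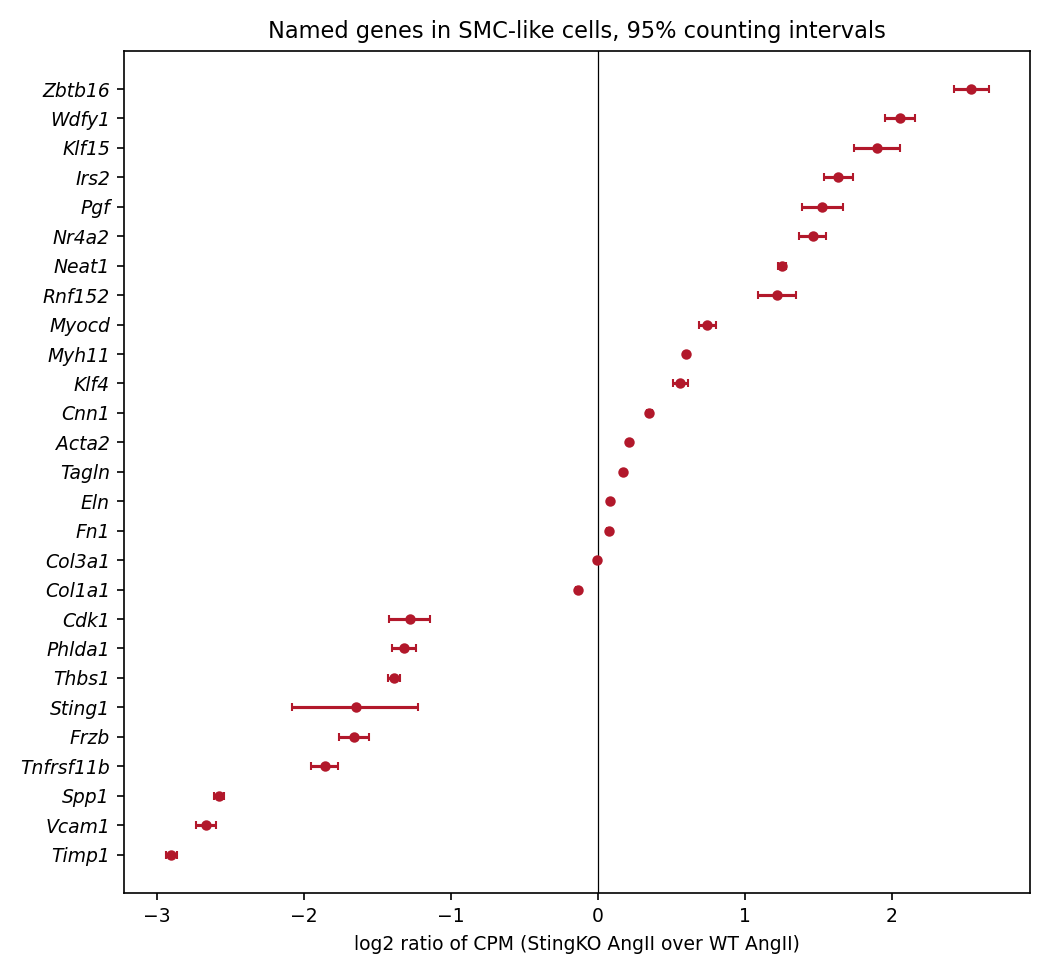
Log2 ratio of CPM in SMC-like cells, StingKO AngII over WT AngII (horizontal axis), for genes named in advance and the 8 highest and 8 lowest among genes that passed the rule for ranking; points are ratios of summed counts and bars exact 95% counting intervals, 1 library per group. Of the genes plotted Zbtb16 is highest at 2.54 and Timp1 lowest at -2.90.

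Median mitochondrial shares were 5.54% and 6.14% in SMC-like, 3.10% and 3.61% in fibroblast-like and 3.00% and 3.75% in mononuclear phagocyte-like cells of WT AngII and StingKO AngII. Median UMIs were 12524 and 11373, 15729 and 13481.5, and 7021 and 6208.5. Immediate early and dissociation stress genes were higher in StingKO AngII for 20 of 21 members in SMC-like cells (median 0.30), all 21 in fibroblast-like cells (0.51) and 20 of 21 in mononuclear phagocyte-like cells (0.48); in SMC-like cells Btg2 had a ratio of 1.11 and Socs3 0.95. All 26 nuclear oxidative phosphorylation genes were lower in StingKO AngII in each of these 3 classes, with medians of -0.22, -0.33 and -0.28, and Sdhd at -0.44 and Ndufa1 at -0.41 in SMC-like cells. In SMC-like cells the unfolded protein list had a median of 0.00, with Chac1 at 0.60 and Dnajb9 at 0.44, and glycolysis genes a median of -0.07, with Ldha at -0.57 and Hk2 at 0.52. In SMC-like cells the resident macrophage list had a median of -0.08 (Mrc1 -0.79, Stab1 -0.77), the lipid-handling list -0.10 (Spp1 -2.58, Trem2 -0.51) and the inflammatory monocyte list -1.39 (Ccr2 -2.01), which turned to 0.074 for members with at least 500 UMIs. Mrc1, Stab1, Trem2 and Ccr2 were at only 3.10, 2.89, 2.06 and 1.24 CPM in SMC-like cells of WT AngII. Free RNA from phagocytes was not weighed for these 4 genes, so their ratios need not describe SMC-like expression.

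In fibroblast-like cells (3462 and 3232), proliferation and inflammatory genes were lower in StingKO AngII. All 30 cell cycle genes were lower, with a median log2 ratio of -0.86, and the thinned share of cells with cell cycle UMIs was 19.2% (17.9 to 20.6) in WT AngII and 11.03% (9.96 to 12.2) in StingKO AngII. Other groupings of the cells were not tried for this list in fibroblast-like cells. Inflammatory cytokine and adhesion genes were lower for 19 of 27 members (median -0.40), with Saa3 at -6.52 and Cxcl5 at -5.48, antigen presentation genes for 15 of 16 (-0.34) and interferon response genes for 20 of 32 (-0.21). By the ranking rule Zbtb16 had the highest ratio, 3.75 (3.57 to 3.95), followed by the renin gene Ren1 at 2.62, Wdfy1 at 2.32 and the adrenomedullin gene Adm at 1.39. The lowest by the rule, which left out Saa3, Cxcl5 and Adipoq, were Cfd at -7.05, Col2a1 at -5.52, Car3 at -3.08 and the lipocalin gene Lcn2 at -2.56. Cfd and Car3 are abundant in fat cells, and the fat cell gene Adipoq was also lower in this class, at 18.4 CPM in WT AngII and 1.11 CPM in StingKO AngII. Without cluster 20, a cartilage-gene cluster of 155 and 37 cells left out after the data were seen, Col2a1 had a ratio of -1.19. The largest clusters of the class were cluster 3 with 960 cells in WT AngII and cluster 7 with 783 cells in StingKO AngII.

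In mononuclear phagocyte-like cells (2127 and 1776), all 13 measured inflammatory monocyte and macrophage genes were lower in StingKO AngII, with a median log2 ratio of -1.78. The list also had lower medians of -1.89 in fibroblast-like cells (10 of 11 lower) and -1.39 in SMC-like cells (6 of 8 lower). The SMC-like median turned to 0.074 for members with at least 500 UMIs. Free RNA from phagocytes and neutrophils was not weighed for this list as a whole in those classes. Their medians thus need not describe their own expression. The inflammatory cytokine and adhesion list was not lower in phagocyte-like cells, with 13 of 23 members higher and a median of 0.11. Their interferon response list had 19 of 33 members lower and a median of -0.03, at percentile 17.8 of random lists. Arg1, the arginase gene, was at 245 CPM in WT AngII and 3.99 CPM in StingKO AngII, a ratio of -5.94 (-6.39 to -5.53), and Slpi, Cxcl3 and the platelet chemokine gene Ppbp had ratios of -4.41, -4.30 and -3.57. Resident macrophage genes were higher for 10 of 12 members (median 0.46), including Lyve1 at 1.58 and Cd163 at 1.00. Lipid-handling genes were lower for 9 of 12 (median -0.65), with Spp1 at -3.14, and glycolysis genes for 15 of 17 (-0.55). Different clusters held most of the class, cluster 2 with 1400 of the WT AngII cells and cluster 5 with 942 of the StingKO AngII cells. Within cluster 2 and cluster 5, taken alone after the data were seen, the inflammatory median was -1.61 and -0.17, and the resident median 0.15 and 0.13. The 4 highest genes by the ranking rule were the haemoglobin genes Hbb-bt, Hba-a1, Hba-a2 and Hbb-bs, and 2 cells of StingKO AngII held 98.7% of that library's haemoglobin UMIs in the class.

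**Figure D3:**
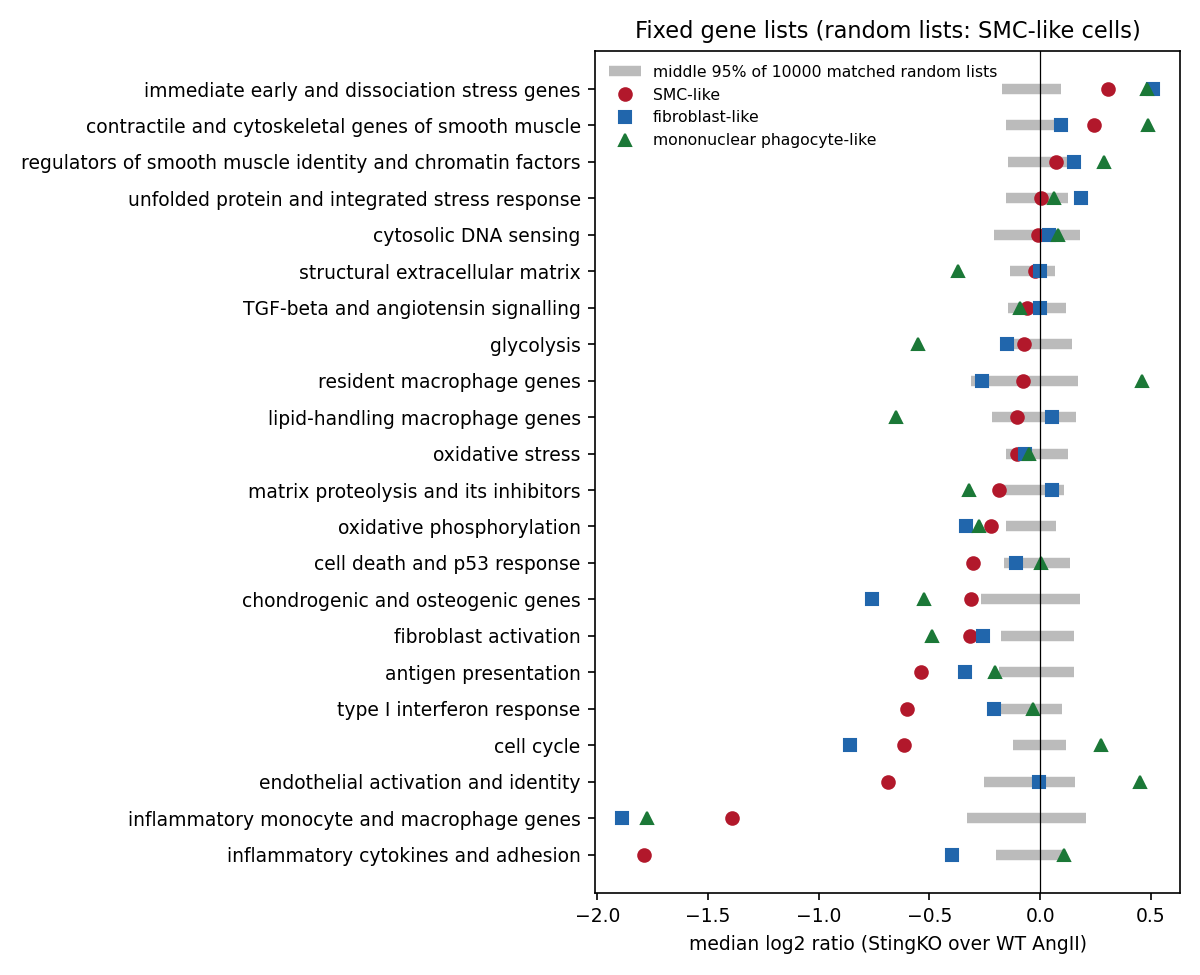
Median log2 ratio (horizontal axis, StingKO AngII over WT AngII) of the measured members of each fixed gene list, as circles for SMC-like, squares for fibroblast-like and triangles for mononuclear phagocyte-like cells; grey bars hold the middle 95% of 10000 matched random lists in SMC-like cells. Inflammatory cytokines and adhesion stand at -1.79 in SMC-like cells, and the cell cycle list lies at -0.61, -0.86 and 0.28 in the 3 classes.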

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

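The count of barcodes with at least 20 neutrophil marker UMIs, the classes of barcodes with at least 5 or 20 and of cells with B cell markers, free RNA from fibroblasts, the mitochondrial bins for inflammatory genes, equal weights for SMC-like clusters, the values for single phagocyte clusters and the share with cluster 10 were chosen only after the results were seen.

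The cell cycle list pointed in opposite directions in different classes, with a median log2 ratio of -0.61 in SMC-like cells (27 of 30 lower), -0.86 in fibroblast-like cells (30 of 30 lower) and 0.28 in mononuclear phagocyte-like cells (19 of 30 higher). The thinned share of phagocyte-like cells with cell cycle UMIs did not rise, at 19.5% (17.8 to 21.3) in WT AngII and 18.7% (16.9 to 20.6) in StingKO AngII. At 1000 UMIs the phagocyte shares were 11.8% and 11.9%. The endothelial activation and identity list had a median of -0.69 in SMC-like cells and 0.45 in mononuclear phagocyte-like cells, the latter over 8 members. Its SMC-like median turned to 0.050 (strict cell filter), 0.080 (thinned) and 0.091 (at least 500 UMIs). These differences between classes were not tested, and with each SMC-like cluster given the same weight the cell cycle median of SMC-like cells was 0.18. Within the phagocyte clusters 2 and 5 taken alone, the cell cycle median was -0.14 and -0.46.

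Cells outside the named classes also gave a signal. Cluster 10, with contractile genes, Msx2 and Rgs5, held 530 cells or 5.37% of WT AngII and 33 cells or 0.325% of StingKO AngII. Cluster 14, led by Cd209a, held 1.71% and 1.04%, and cluster 15, with endothelial markers at low depth, held 1.55% and 0.828%. With 1 library per group, a cluster mostly of 1 library may be a property of that library; counting cluster 10 as SMC-like put the SMC-like share of WT AngII at 36.7%.

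Zbtb16 and Klf15 were higher in StingKO AngII SMC-like cells. For dissociation stress, the median ratio of Zbtb16 over 3 bins of the immediate early share was 2.51 (lowest bin 2.24, highest 2.62), against 2.54 in all SMC-like cells. This lay beyond the bound set against that cause, so the Zbtb16 difference did not follow the immediate early share of single cells. A handling effect on all cells of a library would leave the bins alike, so the test cannot exclude one. Bins are given for Zbtb16 only. A glucocorticoid response is a candidate explanation: the median of 10 response genes such as Fkbp5, Tsc22d3 and Klf9, of which 9 were measured in SMC-like cells, was 0.42 there, 0.92 in fibroblast-like and 0.48 in mononuclear phagocyte-like cells. A different clock phase at tissue collection stays open, because genes of opposite phase differed by 1.05 in SMC-like and 0.93 in fibroblast-like cells but by 0.17 in phagocytes. Whether genotype, handling or time of day set such a response cannot be separated with 1 library per group.

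Neutrophil-like cells were rarer in StingKO AngII. Blood left in the WT AngII tissue stays open: the planned ratios of WT AngII over StingKO AngII, 0.395 (0.110 to 1.18) for cells with at least 20 haemoglobin UMIs and 1.66 (1.46 to 1.90) for cells with at least 2 B cell marker UMIs, were both under the 2 set against it. They were set aside after the values were seen, because 531 of the 581 and 333 of the 359 cells with B cell markers were phagocyte-like and the haemoglobin ratio rests on 5 and 13 cells. For the cell filter, the planned ratio over all barcodes, of those with at least 5 neutrophil marker UMIs, was 1.89 (1.64 to 2.17), which met the range under 3 set for that explanation, but it was set aside after the values were seen because 263 and 229 of its barcodes were fibroblast-like cells, which express the marker G0s2. With at least 20 UMIs the ratio was 12.0 with a lower counting bound of 7.58, above 3 but short of the 10 recorded as the bound against the filter; since the filters had removed 54 of these barcodes in WT AngII and 7 in StingKO AngII, the filter is argued against as the whole cause, a reading made with these values in view, while a part for it and the genotype stay open.

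The SMC-like programme differed, with contractile genes higher and inflammatory genes lower in StingKO AngII. The contractile list was also higher in mononuclear phagocyte-like cells (0.49). Free RNA from SMC-like cells was not weighed there, so whether the shift was particular to SMC-like cells stays open. Free RNA is argued against for the inflammatory list as a whole: for the median member that of phagocytes and neutrophils would account for 1.29% of the WT AngII level and that of fibroblasts, at the highest share their markers allow, for 1.74%, although 6 and 5 of 25 members exceeded 10%. A different mix of SMC-like clusters could account for part: the median over clusters was 0.13 for contractile and -0.91 for inflammatory genes, against 0.24 and -1.79 over all SMC-like cells, and neither value reached the bound set for or against it. RNA quality also cannot be told apart, with medians over 4 bins of mitochondrial share of 0.14 for contractile genes (bins from 0.068 to 0.51) and -1.12 for inflammatory genes (-1.82 in the lowest bin and -0.20 in the highest), because these too lay between the bounds. The effect of the genotype stays open beside these.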

How the results depend on the processing

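Counting cluster 10 as SMC-like, equal weights for SMC-like clusters, single phagocyte clusters and leaving out cluster 20 were chosen after the data were seen; the other alternatives were chosen before the data were examined. No paired analysis was possible because each group is 1 library, and for the same reason no library could be left out. SMC-like shares (WT AngII, StingKO AngII) were 33.6% and 49.0% with the loose filter, 19.1% and 19.0% with the strict filter, 29.3% and 45.6% with doublets kept, 35.4% and 48.8% with separate clustering, and 36.7% in WT AngII with cluster 10. Fibroblast-like shares were 32.8% and 30.0% (loose), 28.9% and 38.5% (strict, where their order turned), 33.6% and 28.8% (doublets kept) and 31.9% and 30.6% (separate). Phagocyte-like shares were 29.2% and 25.9% (strict) and, in StingKO AngII, 18.9% (separate). No neutrophil-like cluster formed with the strict filter, nor in StingKO AngII clustered alone, so these gave no value. Sting1 was at 29.8 and 17.1 CPM with the strict filter. The contractile median was 0.38 (strict), 0.25 (doublets kept), 0.38 (separate), 0.29 (TMM), 0.18 (mean over cells), 0.17 (thinned), 0.26 (cluster 10) and 0.16 (equal weights). The interferon median was -0.20 (strict), -0.73 (doublets kept), -1.07 (separate), -0.46 (mean over cells), -0.31 (thinned), -0.41 (at least 500 UMIs), -0.71 (at least 1 UMI) and -0.37 (equal weights). The inflammatory median was -2.61 (separate) and -1.43 (thinned). The cell cycle median was -0.011 (strict), -0.86 (doublets kept), -2.46 (separate), -0.57 (TMM), -0.42 (mean over cells), -0.39 (thinned), -0.51 (cluster 10) and 0.18 (equal weights, turned). Cycle shares were 4.11% and 2.72% at 1000 UMIs and 3.55% and 2.22% with at least 3 UMIs. Directions also turned for structural matrix at 0.053 (strict), 0.026 (TMM) and 0.049 (equal weights), TGF-beta signalling at 0.076 (strict), the inflammatory monocyte list at 0.074 (at least 500 UMIs), endothelial activation at 0.050 (strict), 0.080 (thinned) and 0.091 (at least 500 UMIs), Col1a1 at 0.020 (strict) and 0.040 (equal weights), Foxm1 at 0.069 (equal weights), and the phagocyte cell cycle list at -0.14 in cluster 2 and -0.46 in cluster 5. For each of these the cause was not tested. Resolution 0.5 and clusters formed with the list and marker genes moved none of the shares and none of these 4 medians beyond their counting intervals. Of 705 values of single genes under alternatives, 694 kept their sign. Of the 705, 456 stayed within their counting intervals, 246 moved beyond them and 3 were reversed against an interval that excluded 0.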

Other observations

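The test of Wdfy1 was chosen only after its values had been seen, as were the platelet and T cell counts.

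Fkbp5, a chaperone partner of the glucocorticoid receptor, was at 4.59 and 18.4 CPM in SMC-like cells, 23.8 and 52.7 CPM in fibroblast-like cells and 19.5 and 132 CPM in mononuclear phagocyte-like cells of WT AngII and StingKO AngII. Other genes of the glucocorticoid list went the other way in mononuclear phagocyte-like cells, with log2 ratios of -0.18 for Sgk1 and -1.06 for Ddit4. Platelet and T cell markers were seen in more WT AngII cells: 1.99% and 0.582% had at least 2 platelet marker UMIs, and 0.851% and 0.325% at least 2 T cell marker UMIs. Most of these cells lay in named classes other than platelets and T cells.

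Wdfy1 (chromosome 1, 79702262 to 79776143) was higher in StingKO AngII in the 3 classes compared, with log2 ratios of 2.05 in SMC-like, 2.32 in fibroblast-like and 1.52 in mononuclear phagocyte-like cells. A variant carried with the Sting1 allele on chromosome 18 was the hypothesis tested. Of 95 genes at least 1.5 times higher or lower in the 3 classes, 2 were on chromosome 18, one of them Sting1 itself, a share 0.840 times (0.102 to 2.95) that among all genes measured. Wdfy1 lies on another chromosome, which was known before the test. The hypothesis stays open, because the interval rests on 2 genes and a variant near Sting1 that acts on Wdfy1 from there was not tested.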
